A study of Mus musculus with 4 samples.

How the data were processed

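Gene expression was measured in mouse trophoblast stem (TS) cells, the self-renewing precursors of the trophoblast, which forms the outer part of the placenta. The labels list 4 samples. They are 1 female line that carries the IVS mutation of Xist (line T5, from a DBA/2 x Xist IVS/Y cross) and 1 wild-type female line (DD1, DBA/2 x C57BL/6), each at day 0 and at day 6. What was done to the cells between the days is not stated. Total RNA was isolated with TRIzol, and 500 ng was labelled with the dye Cy3 for hybridisation to Agilent whole-genome arrays, per the labels' protocols. Each sample comes with 2 arrays whose relation (a repeat hybridisation, a second labelling or a second culture) is not given. The groups are IVS day 0, IVS day 6, WT day 0 and WT day 6, with 1 sample each. Per the file headers, all 4 day 0 arrays lie on 1 slide and all 4 day 6 arrays on a second slide, scanned separately, so day and slide cannot be told apart, whereas both lines stand side by side on each slide.

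The scanner values are spot intensities that the authors made with Agilent Feature Extraction 10.5.1.1, per the file headers and labels. In these values the background of each spot has been subtracted and the signal detrended within its array, and nothing has been scaled between arrays. The deposited value table holds log2 values of 572 probes, of which 310 were paired with an X-linked gene, 2 with an autosomal gene and 260 with no gene, centred per probe on a reference that neither the labels nor the table state. Differences between its columns tracked the log2 scanner values of the same probes with a Pearson r of 0.975 to 0.995 across probes and slopes of 0.931 to 0.991, and the medians of its columns were -0.12 (IVS day 0), 0.33 (IVS day 6), -0.17 (WT day 0) and 0.04 (WT day 6). That table served only as an alternative, since it holds only 2 probes of autosomal genes. The authors' selection of those probes kept expressed genes: 99.7% of their named probes were well above background on both arrays of at least 1 sample, against 43.4% of the 325 other X-linked probes.

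Control spots were left out, which left 43803 probes per array. The processed signal was converted to log2, the 75th percentile of each array was subtracted, and spots flagged as outliers (2 to 11 per array) were set to missing. All levels below are therefore log2 values relative to the 75th percentile of the array. Probes carry RefSeq accessions, which were looked up in a RefSeq gene table of assembly GRCm38.p6. The grid of the arrays names the older build mm9, so the gene table was used for symbols, chromosome membership and gene order along the X, and no coordinates are given. Of the 43803 probes, 16751 (38.2%) were paired with 1 gene and 27052 with none. They gave 13137 genes, of which 489 were X-linked, 12639 autosomal and 9 Y-linked. Where a gene had several probes (2812 genes), the brightest over all arrays was used. A gene counted as detected in a comparison when the scanner software called it well above background on both arrays of at least 1 of the samples compared. Where the other sample was not above background on either array, the fold is given as a bound ("at least"), for which each of its arrays was raised to the lowest level called above background on that array where it lay below. The sample above background enters a bound as the mean of its 2 arrays, so the bound does not cover their spread. For an array no counting depth exists. Between 51.83% and 65.83% of the probes were well above background per array, no probe was saturated, and the number of arrays limits the precision.

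The 2 arrays of a sample were averaged before any comparison, and SD of arrays means the standard deviation of those 2 values. With 1 sample per group, no test of IVS against WT at 1 day, or of day 6 against day 0 in 1 line, was possible. For these comparisons a gene was counted when the sample means differed by at least 1.5-fold (lines) or 2-fold (days) and both arrays of 1 sample lay beyond both arrays of the other, and the members of gene lists were counted by the same rule. By chance the arrays of an unchanged gene do not overlap in 33.3% of cases. The median difference of all X-linked genes was placed among the medians of 10000 random lists of autosomal genes of the same size, drawn from 20 bins of mean level. That of a gene list was placed among 10000 random lists of the other detected genes on any chromosome, drawn likewise. Where the list was X-linked, it was also placed among 10000 random X-linked lists drawn from 4 bins. Lists with fewer than 5 detected genes were given no percentile. The percentiles treat genes as independent, which they are not, and they describe a list and are not tests of the lines. The only test was an additive fit (line plus day) with limma 3.58.1 in R 4.3.3 on the 4 sample means. It used eBayes with an intensity trend, 1 residual degree of freedom (prior 3.908) and Benjamini-Hochberg adjustment over the 10221 genes detected in at least 1 sample, with a threshold of 0.05. In that fit the days stand in for replicates of the line. Its residual is the change of the line difference between the days, so its SE does not use the spread between the arrays of a sample. Because each genotype is represented by 1 cell line, every comparison of IVS with WT is a comparison of these lines, and the mutation cannot be told apart from any other difference between them. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

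The rule for named genes, the 15 gene lists, the thresholds and the alternatives were fixed before the data were examined. Named for each IVS minus WT difference were Xist, the 10 X-linked genes with the largest positive and the 5 with the largest negative difference, and 5 autosomal genes in each direction. For each change from day 0 to day 6 the 10 largest changes in each direction were taken. Xist aside, these genes were picked among detected genes whose arrays did not overlap. For the additive fit the 10 genes of lowest p in each direction were taken, with no rule on overlap. Up to 4 members of a list could be named. Genes near Xist were to be those within a fixed distance. They were taken instead as the 100 detected genes nearest in gene order, since the builds differ. The alternatives tried were no scaling, scaling to the autosomal median or to the control genes, quantile normalization, normexp background correction (offset 50) of the median spot signal, no detection filter, a filter on all 8 arrays, the mean of a gene's probes, other thresholds, either array of each sample alone and the authors' value table. Normexp had been planned on the mean spot signal, which the files do not hold. Added after the data had been seen were the X-linked minus the autosomal median, the medians of the 19 autosomes, leaving out either IVS array alone, limma with each of the 8 arrays taken as a sample, the probes without a gene name, 5 further gene lists and the choice of markers drawn per array. The spread set beside the change of the line difference was widened from 4 to all 16 pairings of single arrays after its verdicts had been seen.

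The additive fit was tested on simulated samples of the same 10221 genes, with 200 genes changed between the lines and variances drawn from the fitted prior. Over 20 runs, it recovered 3.9% of genes changed by 1 log2 unit, 48% of those changed by 2, 84.3% by 4 and 91.3% by 6, and 6% of its calls were false. With variances set to the shrunken estimates, which was the first simulation run, 19.3% of the calls were false, and the draw from the prior was added after that result. Without the intensity trend and with variances drawn from the prior, the recovery was 0.5% at 2 log2 units, 63% at 4 and 87.2% at 6. It made 77.3 calls per run on average, of which 2.6% were false. On the data themselves the fit without the trend called 0 genes for the line. The simulated noise thus differs from that of the data, and these rates cannot be carried over to the calls in the data. The counting rule was tested on 10035 simulated genes of the day 0 line comparison. It counted 88% of genes changed by 1 log2 unit, all 50 genes at each larger size, and 8.1% of unchanged genes. These simulated genes held only the spread between the arrays of a sample, so 8.1% is a rate for array noise and leaves out variation between cultures.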

Results

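Xist is the non-coding RNA that coats and silences 1 X chromosome in female cells. The study asked how a mutation of this gene, called IVS, affects silencing of X-linked genes in TS cells. The data are 8 one-colour arrays of 4 samples, a mutant line (IVS) and a wild-type line (WT) at day 0 and at day 6, with 2 arrays per sample. There were no replicate samples, and errors given as SD are those of the 2 arrays of a sample. The arrays of a sample resembled each other less in the mutant line. Pearson's r between them across genes was 0.973 in IVS day 0 and 0.967 in IVS day 6, against 0.993 in WT day 0 and 0.997 in WT day 6. At least 1.5-fold apart between the 2 arrays were 30.9% of genes in IVS day 0, 25.1% in IVS day 6, 7.45% in WT day 0 and 2.18% in WT day 6.

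Xist RNA was abundant in all 4 samples and slightly lower in the mutant line. Its level was 4.05 (SD 0.18) in IVS day 0 and 4.49 (SD 0.02) in WT day 0, which is 1.36-fold lower in IVS. At day 6 it was 3.82 (SD 0.05) in IVS and 4.30 (SD 0.05) in WT, 1.40-fold lower in IVS. The size of that day 6 difference depended on the scaling, with a log2 value of -0.48 here, -0.113 with no scaling and -0.92 with control-gene scaling. Neither IVS array overlapped a WT array of the same day. The position of the probe relative to the mutated part of the transcript is not known, so the value does not check the genotype labels. Of 9 Y-linked genes on the array, 6 were not above background on any array. Sry was called above background on 5 arrays, Zfy1 on 4 and Ddx3y on 1, and none of their values exceeded -3.83.

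**Figure D1:**
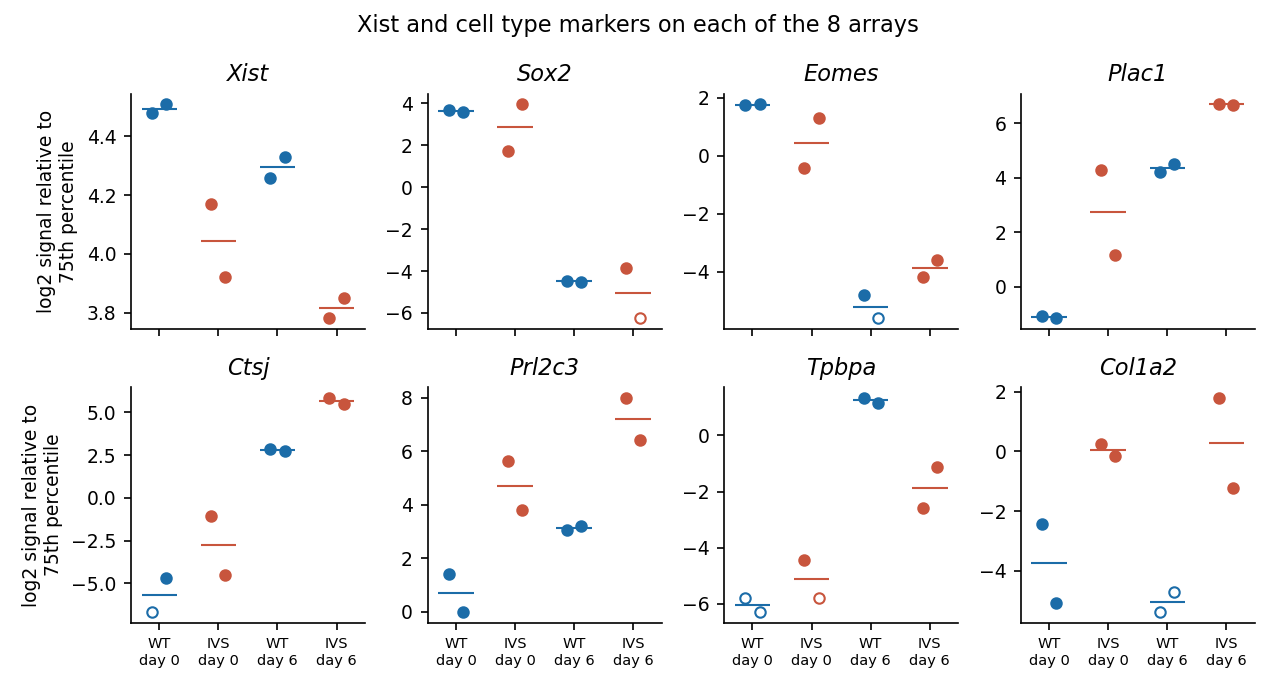
Level of Xist and of 7 marker genes on each of the 8 arrays (vertical axes: log2 signal relative to the 75th percentile of the array, with a separate scale per gene; groups on the horizontal axis; line: mean of the 2 arrays; open points: not above background). Xist is lower on the IVS arrays than on the WT arrays of the same day, and the IVS day 0 arrays are apart for Sox2 (1.75 and 3.96) and Plac1 (4.29 and 1.17).

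The first comparison asked whether X-linked genes were expressed at a higher level in the mutant than in the wild-type line. At day 0, 88 of 322 detected X-linked genes (27.3%) were at least 1.5-fold higher in IVS and 43 (13.4%) at least 1.5-fold lower. At day 6, 88 of 277 (31.8%) were higher and 38 (13.7%) lower. Of the autosomal genes, 17.3% were higher and 13.1% lower at day 0, and 19.5% were higher and 16.5% lower at day 6. The median X-linked gene was 1.14-fold higher in IVS at day 0 and 1.22-fold higher at day 6. The median log2 difference was 0.19 for the X against 0.09 for 9711 autosomal genes at day 0, and 0.29 against 0.07 for 9033 autosomal genes at day 6. The X-linked median thus exceeded the autosomal median by 0.101 at day 0 (0.06 to 0.205 over the 4 pairs of arrays, 99.86th percentile of random autosomal lists) and by 0.22 at day 6 (0.134 to 0.239, above every random list). Single autosomes were placed likewise among random lists from the other autosomes. Chromosomes 14 and 15 then lay above every list at both days, and chromosomes 3, 10 and 13 below every list. These percentiles therefore do not set the X apart from the autosomes. At day 0, 56.5% of X-linked genes lay above the autosomal median, and at day 6, 61.7%. Scaling to the control genes, of which 3 of 8 were higher in IVS at either day, moved the median of all genes from 0.09 to -0.16 at day 0 and from 0.07 to -0.37 at day 6, and no scaling moved it to -0.11 and 0.44. The X-linked median itself then turned to -0.065 and -0.154 with control-gene scaling and to -0.012 at day 0 with no scaling. With control-gene scaling 61 X-linked genes were higher and 65 lower at day 0, and 41 higher and 76 lower at day 6. Without IVS array 1 the day 0 excess was 0.226, and with array 1 left out of every sample the day 6 excess was 0.13. With no filter on dim probes the excess was 0.193 at day 0 and 0.09 at day 6, so the order of the days turned. For 259 and 255 detected probes of the authors' table that have no gene name here, the excess over the autosomal median was only 0.033 and 0.03. It was 0.089 and 0.133 over the other unnamed probes.

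Among single X-linked genes, the differences in favour of IVS reached 52.1-fold at day 0, for Fnd3c2, a gene with fibronectin type III domains. This gene was 11.2-fold higher at day 6. The neighbouring armadillo-repeat genes Armcx2 and Armcx1 were 35.4-fold and 17.7-fold higher at day 0, each with only 1 of the 2 WT arrays above background (SD of the WT arrays 3.41 and 1.78). Armcx2 was at least 9.77-fold higher at day 6 (SD of the IVS arrays 2.26). Plac1, a placenta-specific gene needed for normal placental growth, was 14.4-fold higher at day 0 and 5.0-fold at day 6, but its IVS day 0 arrays were far apart (SD 2.20). Also higher at day 0 were Gria3, a glutamate receptor subunit (13.9-fold, 1 of 2 WT arrays above background, SD 2.40), Sash3 (5.96-fold), Mid1 (at least 5.3-fold), the chromatin remodeller Smarca1 (at least 3.62-fold), Lpar4 (at least 2.66-fold) and Spry3 (at least 2.15-fold). At day 6 the spermine synthase gene Sms (5.78-fold), Taf7l (4.97-fold), the ubiquitin-conjugating enzyme gene Ube2a (3.34-fold), Vegfd (8.58-fold, 1 of 2 WT arrays above background, SD of the IVS arrays 2.00), Tceal3 (at least 4.9-fold), Xlr (at least 4.62-fold) and Sowahd (at least 1.82-fold) were among the 10 largest differences. Lower in IVS were Hdx (at least 17.4-fold at day 0, at least 6.93-fold at day 6) and the near-identical genes Ssxb1 and Ssxb2, whose probes may detect either (74.1-fold and 59.4-fold at day 0 with 1 of 2 IVS arrays above background, and at least 19.5-fold and at least 27.1-fold at day 6). Gpc3, a cell surface proteoglycan, was 23.0-fold lower at day 0 with 1 IVS array above background, Gpm6b at least 2.59-fold lower at day 0, and Tceal8 (21.6-fold, SD of the IVS arrays 2.22) and Rps6ka6 (12.9-fold) lower at day 6.

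Groups of X-linked genes differed. Of 33 X-linked housekeeping genes, 12 were higher and 1 lower at day 0 (median 0.36, 99.63rd percentile of random lists, 86.03rd of X-linked lists). That median was 0.1 with control-gene scaling and 0.15 with no scaling. At day 6, 17 were higher and 2 lower (median 0.65, above every random list, 99.35th percentile of X-linked lists, 0.21 with control-gene scaling). Among them were Xiap, an inhibitor of apoptosis (2.64-fold and 2.79-fold), Emd (2.54-fold at day 0), the ribosomal protein gene Rpl10 (2.41-fold at day 0), Hmgn5 (3.19-fold at day 6) and Timm17b (2.90-fold at day 6), whereas Phf8 was 3.73-fold and Maoa 2.78-fold lower at day 6. Of 9 detected genes known to escape X inactivation, which are expressed from both X chromosomes in normal cells, 2 were higher and none lower at day 0 (median 0.42, 74.53rd percentile of X-linked lists). Of 7 at day 6, 2 were higher, Utp14a (1.82-fold) and Pbdc1 (1.65-fold), and none lower (median 0.26, 38.39th percentile; -0.17 with control-gene scaling). The X-linked placental and reproductive homeobox genes went the other way at day 0, with 1 of 10 higher and 5 lower (median -1.17, below every random list; -0.51 with normexp). Their lower members included Esx1 (4.84-fold), Cited1 (2.96-fold) and Gpc4 (at least 2.12-fold). At day 6, 2 of 8 were higher and 3 lower (median -0.18, 4.92nd percentile; 0.19 without scaling), with Esx1 4.70-fold lower. Of the germline and multicopy genes, 2 of 6 were higher at day 0 (median 0.39) and 3 of 7 at day 6 (median 0.24, -0.20 with control-gene scaling), none lower. In the X-inactivation centre, the region around Xist, 5 genes were detected at day 0 (median -0.44), of which Rlim was 1.57-fold higher and Nap1l2 at least 1.77-fold lower. The 3 detected at day 6 were all within 1.5-fold (median -0.15, 0.22 without scaling).

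The excess of the X was compared with that of each autosome and with distance from Xist. At day 0 the X ranked 4th and at day 6 3rd of 20 chromosomes from the highest median. Relative to the median of all autosomal genes, chromosome 14 was higher in IVS by 0.264 at day 0 and 0.262 at day 6, and chromosome 15 by 0.266 and 0.364. Chromosomes 3 (-0.282 and -0.315), 10 (-0.274 and -0.225) and 13 (-0.30 and -0.208) were lower. The SD of the 19 autosomal medians was 0.153 and 0.154 between the lines, 0.06 between the days in either line, and 0.01 to 0.038 between the arrays of a sample. The 100 detected genes nearest Xist had a median of 0.108 and the other 222 a median of 0.242 at day 0, a difference of -0.135 (3.93rd percentile of lists of X-linked genes). At day 6 it was -0.077 (26.38th percentile). The day 0 difference was 0.031 with no detection filter and 0.14 in the authors' value table, and the day 6 difference was -0.216 with array 1 left out of each sample and 0.08 in that table.

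**Figure D2:**
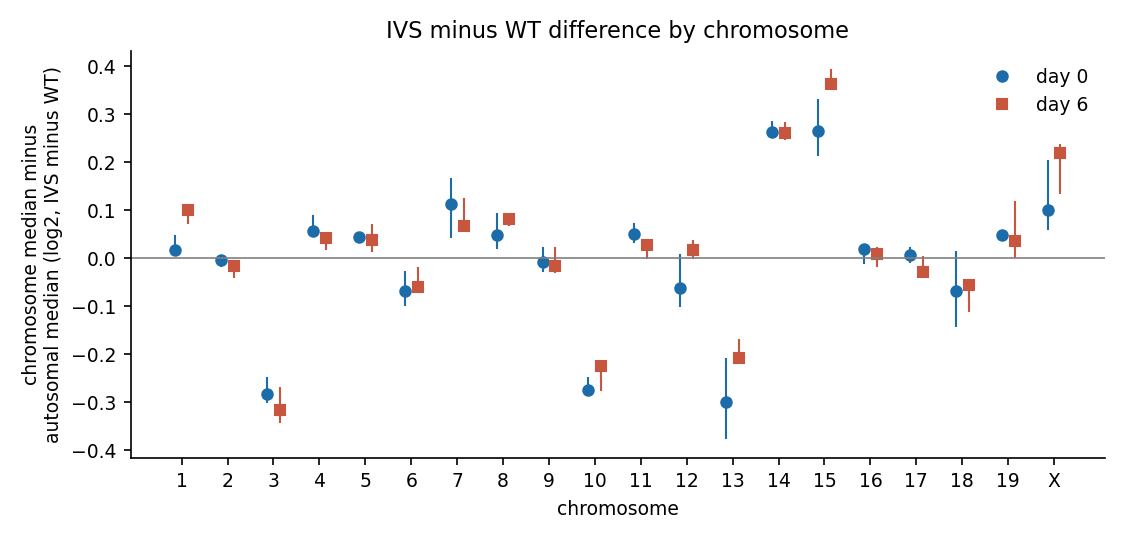
Median IVS minus WT difference of the detected genes of each chromosome, less the median of all autosomal genes (vertical axis, log2), for chromosomes 1 to 19 and X (horizontal axis). Points are sample means and lines span the 4 pairs of arrays. The X lies at 0.101 (day 0) and 0.22 (day 6), between chromosomes 14 and 15 above and most other chromosomes below.

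Single autosomal genes also differed between the lines. The amino acid transporter gene Slc38a4, which is imprinted in placenta, was 172-fold lower in IVS at day 0 and 182-fold lower at day 6. The adaptor subunit gene Ap1m2 (95.8-fold and 110-fold) and the tight junction gene Cldn6 (84.0-fold and 86.4-fold, 1 of 2 IVS arrays above background at day 6) were also lower at both days. Vnn1, a pantetheinase, was at least 109-fold lower at day 0 and 214-fold lower at day 6 with 1 of 2 IVS arrays above background. Rab19 was at least 31.9-fold lower at day 0, and Igfbp2 100-fold lower at day 6 (SD of the IVS arrays 2.5). Higher in IVS at day 0 were the peptide transporter gene Slc15a2 (at least 63.1-fold), the placental prolactin-family genes Prl8a9 (133-fold) and Prl2a1 (88.0-fold), the surface protein gene Msln (90.4-fold) and the hormone gene Cck (82.2-fold, SD of the WT arrays 3.01). At day 6 these were the matrix gene Efemp1 (at least 101-fold), Cck (at least 41.5-fold), the growth factor gene Ptn (at least 42.9-fold), the secreted protein gene Spp1 (126-fold, SD of the IVS arrays 2.56) and Lztfl1 (91.4-fold, 1 of 2 WT arrays above background).

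Trophoblast marker groups were not balanced between the lines at day 0. All 7 detected giant cell genes were higher in IVS (median 4.03, above every random list; 2.64 with normexp), among them Prl4a1 (56.8-fold, 1 of 2 WT arrays above background, SD of the IVS arrays 2.14), Prl6a1 (at least 35.5-fold) and Prl2c3 (16.3-fold). Of 10 stem cell genes, 2 were higher and 3 lower (median -0.57, 0.01st percentile), with Id2 4.39-fold (SD of the IVS arrays 2.35), Eomes 2.49-fold and the growth factor receptor gene Fgfr2 1.98-fold lower and Ets2 1.97-fold higher. These groups also differed between the 2 arrays of IVS day 0. On array 1, 8 of 10 stem cell genes were at least 1.5-fold lower than on array 2 (median -1.70) and 6 of 7 giant cell genes were higher (median 1.83). At day 6, 6 of 10 giant cell genes were higher in IVS and 2 lower (median 2.06, above every random list), with Prl4a1 26.1-fold and Prl3d2 20.8-fold higher and Prl6a1 at least 7.27-fold lower. The stem cell genes then had 5 higher and 2 lower (median 0.28, -0.16 with control-gene scaling), with Esrrb 4.95-fold higher and Fgfr2 7.22-fold lower. The syncytiotrophoblast and chorion genes were lower at day 6 for 7 of 8 (median -1.19, 0.05th percentile), including their regulator Gcm1 (at least 6.49-fold), Gjb2 (log2 -3.40, 1 of 2 IVS arrays above background) and Synb, which codes for the cell fusion protein syncytin-B (6.02-fold). At day 0, 2 of 8 were higher and 3 lower (median -0.25). Spongiotrophoblast and glycogen cell genes were mixed, with 3 of 7 higher and 1 lower at day 0 (median 0.53, 0.27 with control-gene scaling) and 4 of 11 higher and 4 lower at day 6 (median -0.57, -0.28 with normexp). In that group Prl8a9 was 32.7-fold higher and Tpbpa, the classical spongiotrophoblast marker, 8.66-fold lower at day 6.

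Markers of other cells and of imprinting differed as well. Of 8 detected fibroblast feeder markers, 6 were higher in IVS and none lower at day 0 (median 2.35), and 5 were higher and 2 lower at day 6 (median 2.64), both above every random list. With normexp these medians were 1.42 and 0.89. The collagen genes Col1a2 (log2 3.81 at day 0, at least 34.9-fold at day 6), Col1a1 (6.12-fold and 17.2-fold) and Col6a1 (7.43-fold and 21.1-fold) were among them, with an SD of 2.08 to 2.13 between the IVS day 6 arrays. These markers also differed between arrays of a sample, by a median of 2.98 in IVS day 6 and 1.72 in WT day 0. The imprinted autosomal genes had 1 of 9 higher and 4 lower at day 0 (median -0.34) and 2 higher and 5 lower at day 6 (median -1.12, 0.01st percentile; -0.68 with normexp). Mest was 4.83-fold lower at day 0, with an SD of 2.25 in IVS, and 66.8-fold lower at day 6 with 1 of 2 IVS arrays above background. Snrpn was 3.48-fold and 4.31-fold lower, and Airn 4.38-fold and 2.82-fold higher. Of the pluripotency genes, 0 of 7 were higher and 2 lower at day 0 (median -0.42), and 3 of 6 were higher and 1 lower at day 6 (median 0.47, 0.03 with control-gene scaling). Of the primitive endoderm genes, 0 of 10 were higher and 3 lower at day 0 (median -0.24), and 3 of 7 higher and 1 lower at day 6 (median -0.18, 0.19 without scaling). Of 20 X-inactivation and Polycomb factors, 2 were higher and 3 lower at day 0 (median 0.05, -0.15 without scaling), and 3 higher and 2 lower at day 6 (median 0.25, -0.19 with control-gene scaling). Dnmt3b, a DNA methyltransferase, was 2.49-fold and 2.03-fold lower. Of 8 control genes, 3 were higher and 1 lower at both days (medians 0.07 and 0.08, -0.13 at day 0 without scaling, -0.36 at day 6 with control-gene scaling), with the lysosomal enzyme gene Gusb 3.07-fold and 11.0-fold higher.

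The second comparison, day 6 against day 0 within each line, followed the culture over time, with day and slide confounded. In WT, 1730 genes were at least 2-fold higher and 1363 at least 2-fold lower at day 6. In IVS, 1494 were higher and 1208 lower. Most stem cell genes were lower and most giant cell genes higher at day 6 in both lines, here too counted at 2-fold. Of 10 stem cell genes, 8 were lower in each line (medians -3.18 in WT and -3.29 in IVS, below every random list), whereas 1 was higher in WT and 2 in IVS. Sox2 was 282-fold lower in WT and 241-fold lower in IVS, Esrrb 146-fold and 22.1-fold, and Eomes 125-fold and 20.1-fold, with 1 of 2 day 6 arrays above background for Sox2 in IVS and for Eomes in WT. Giant cell genes were higher for 9 of 10 in WT (median 5.38) and 8 of 10 in IVS with 1 lower (median 4.55). The rises were led by the placental cathepsin genes Ctsj (357-fold in WT, with 1 of 2 day 0 arrays above background, and 346-fold in IVS, SD of the day 0 arrays 2.45) and Ctsr (207-fold in WT, likewise, and at least 115-fold in IVS). With normexp these medians were 2.46 and 2.05. Spongiotrophoblast genes were higher for 9 of 11 in WT (median 2.64, 1.17 with normexp) and 5 of 9 in IVS (median 2.03). Tpbpa was at least 141-fold higher in WT and 9.40-fold higher in IVS, with 1 of 2 IVS day 0 arrays above background. Syncytiotrophoblast genes were higher for 5 of 8 in WT (median 1.52, 0.62 without scaling) and 2 of 7 in IVS with 1 lower (median 0.75, 0.42 without scaling).

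**Figure D3:**
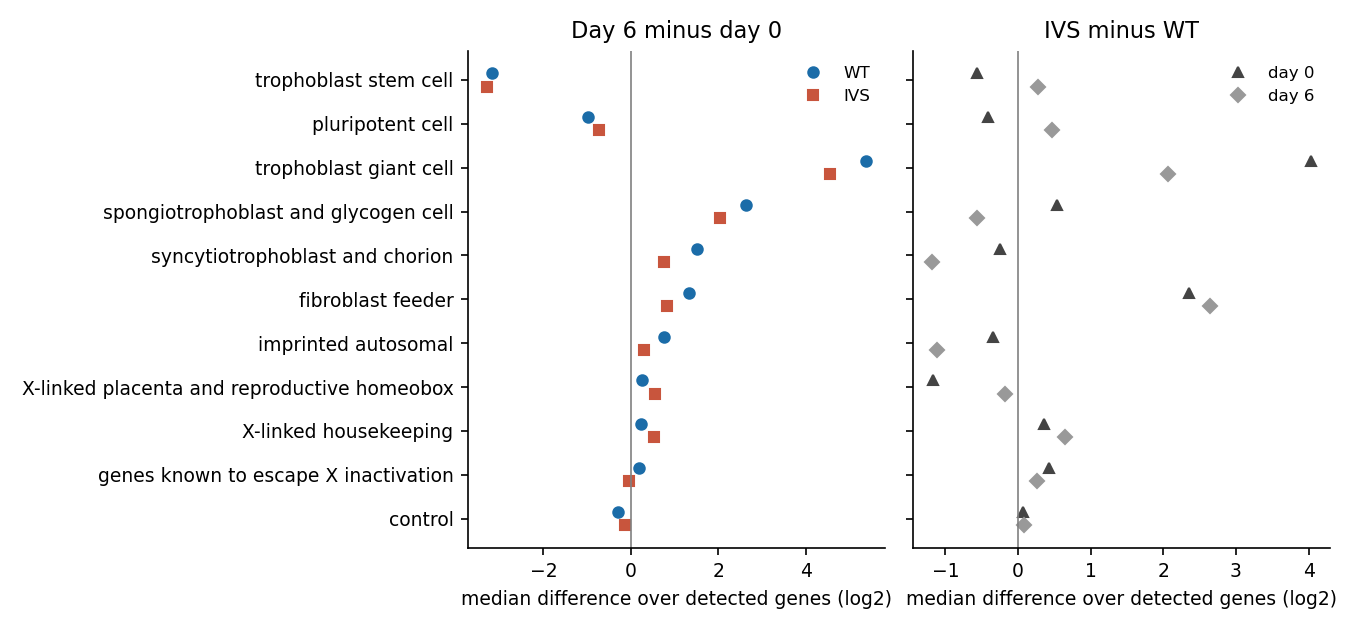
Median log2 difference over the detected members of 11 gene lists (horizontal axes), for day 6 minus day 0 in each line and for IVS minus WT at each day. Stem cell genes lie at -3.18 and -3.29 and giant cell genes at 5.38 and 4.55 for day 6 minus day 0; with normexp the giant cell values were 2.46 and 2.05.

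Further genes with the largest positive differences in WT were Stra6, the retinol uptake receptor gene (at least 71.5-fold), Slco4a1 (140-fold), Lonrf3 (131-fold), Myl4 (127-fold), Prl4a1 (122-fold, 1 of 2 day 0 arrays above background), Prl7d1 (at least 53.3-fold) and Plac8 (106-fold, likewise). In IVS they were Ceacam9 (244-fold, SD of the day 6 arrays 2.04) and Entpd1 (168-fold, SD of the day 0 arrays 2.69), each with 1 of 2 day 0 arrays above background, Ccrl2 (at least 23.7-fold), Prl7a1 (99.0-fold), Plac8 (78.5-fold), Xdh (65.7-fold), and Chdh (71.2-fold) and Pthlh (63.3-fold), again with 1 day 0 array above background. Lower at day 6 in WT were the hormone precursor gene Calca (at least 801-fold), the nuclear receptor gene Nr0b1 (at least 172-fold), Tmem114 (324-fold, 1 of 2 day 6 arrays above background), Ccdc3 (131-fold), Nexmif (at least 29.0-fold), Matn2 (at least 41.8-fold) and the retinoic acid-degrading enzyme gene Cyp26a1 (96.7-fold). In IVS, Cyp26a1 (126-fold), the zinc finger gene Zic3 (83.8-fold, SD of the day 0 arrays 2.74) and Ccdc3 (65.0-fold) were lower, each with 1 of 2 day 6 arrays above background. Also lower in IVS were Nr0b1 (at least 25.1-fold, SD of the day 0 arrays 2.64), Fbp2 (at least 12.7-fold), Tm6sf1 (at least 10.3-fold) and Nptx1 (at least 13.5-fold). So were Capn6 (at least 9.83-fold, SD of the day 0 arrays 2.37) and Bves (35.8-fold, SD of the day 0 arrays 2.09).

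The medians of the other lists were nearer 0 in WT. Pluripotency genes had medians of -0.98 in WT (-0.51 with normexp) and -0.73 in IVS, and fibroblast markers of 1.33 (0.43 without scaling) and 0.83. Imprinted genes had medians of 0.76 and 0.31 (-0.13 and -0.02 without scaling), X-linked placental genes of 0.25 (-0.64 without scaling) and 0.55, and X-linked housekeeping genes of 0.23 (-0.66 without scaling) and 0.53. The medians in WT and IVS were 0.18 and -0.04 for the escape genes, -0.35 and 0.06 for the germline genes, -0.12 and -0.38 for primitive endoderm genes, 0.03 and 0.10 for the Polycomb list, and -0.30 and -0.13 for the control genes. In the X-inactivation centre, the median over 5 genes was -0.46 in WT and over 4 genes 0.07 in IVS. The medians of the escape, primitive endoderm, Polycomb and X-inactivation centre lists in both lines, and of the germline genes in IVS, took the other sign under at least 1 other scaling. No scaling moved the median of all genes from 0.13 to -0.77 in WT and from 0.10 to -0.23 in IVS. It left 532 genes 2-fold higher and 3943 lower in WT, and 939 higher and 1836 lower in IVS. Normexp moved the median of all genes to 0.26 in WT, and scaling to the autosomal median moved it to 0.01 and -0.06. X-linked genes as a whole had a median difference of -0.03 against 0.13 for autosomal genes in WT, and of -0.06 against 0.11 in IVS. The X-linked minus autosomal median was -0.157 in WT (0.79th percentile) and -0.164 in IVS (1.78th percentile). It was 0.137 in WT with no detection filter and 0.029 in IVS with array 2 left out of each sample.

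The change of the IVS minus WT difference from day 0 to day 6 had a median of 0.04 over 330 X-linked genes and -0.02 over 9889 autosomal genes (98.08th percentile of random lists). The 16 pairings of arrays gave it an SD of 0.075, more than the value itself, so no change of the X between the days was resolved.

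The additive fit tested what the lines had in common at both days. For the line, 542 of 10221 genes passed an adjusted p of 0.05 with limma, 296 of them higher in IVS and 246 lower, and 2480 passed an unadjusted p of 0.05. X-linked genes were 29 of these (8.79% of 330), 18 higher and 11 lower, and autosomal genes 513 (5.19% of 9889). Genes higher in IVS included Prl2c3 (16.7-fold, log2 4.06, SE 0.16, adjusted p = 0.00501), the calcium-binding protein gene S100a4 (11.6-fold, adjusted p = 0.0109), Prl4a1 (38.5-fold), Fxyd5 (5.12-fold), Zbtb8a (20.7-fold), Tppp3 (6.60-fold) and the caveolar protein gene Cavin2 (21.2-fold). Cck (adjusted p = 0.0109), Tm4sf1 and Rpl39l (adjusted p = 0.0173) passed as well, with WT day 6 not above background, so no fitted fold is given. Lower were Slc38a4 (177-fold, log2 -7.46, SE 0.21, adjusted p = 0.00437), Igfbp2 (82.5-fold), Ap1m2 (103-fold), Cldn6 (85.2-fold), the interferon regulatory factor gene Irf7 (24.0-fold, adjusted p = 0.00501) and the T-box factor gene Tbx3 (31.0-fold). Vnn1 (adjusted p = 0.00888), Ssxb2, Mfsd9 and Slc34a2 (adjusted p = 0.0109) passed as lower with IVS not above background at 1 or both days, likewise without a fold. Each of these 20 genes had the same direction at both days, which choosing the lowest p favours. Their SEs do not use the spread between the arrays of a sample. For Prl2c3 the arrays read 5.63 and 3.8 in IVS day 0, and 8.0 and 6.42 in IVS day 6. Of the giant cell list 6 of 10 genes passed as higher in IVS, and of the X-linked housekeeping list 4 of 33 passed as higher and none as lower, or 13 and 1 adjusted over the list alone. The fibroblast list had 3 of 10 higher, 6 adjusted over the list alone. The X-linked placental list had 1 of 10 higher and 3 lower either way, and the germline list 1 of 7 higher. Of the stem cell genes 1 passed as higher, and 2 as higher and 3 as lower adjusted over the list alone. The counts higher and lower were 1 and 1 for spongiotrophoblast genes (2 and 1 adjusted over the list alone), 0 and 2 for syncytiotrophoblast genes (0 and 5), 1 and 2 for imprinted genes (1 and 3), 0 and 1 for the pluripotency and Polycomb lists either way, and 0 and 0 for the control genes (3 and 1). No gene of the escape, X-inactivation centre or primitive endoderm lists passed. The line count was 0 with eBayes without the intensity trend (2099 at an unadjusted p of 0.05), 0 with array 1 left out of every sample (1644 unadjusted), and 0 with array 1 left out of the IVS samples alone (1799 unadjusted), so it rests on those choices. Without scaling it was 877, and with scaling to the control genes 368, of which 29.9% were higher, against 54.6% above.

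For the day, 2496 genes passed with limma, 1652 higher and 844 lower at day 6 (4239 unadjusted). Without scaling only 18.7% of the passing genes were higher, against 66.2% here, and the count was 0 without the trend (3709 unadjusted). It was 523 with array 1 left out of every sample and 402 with array 1 left out of the IVS samples alone. Ctsj rose 352-fold (log2 8.46, SE 0.24, adjusted p = 0.004), followed by Sgk2 (44.3-fold), Plac8 (91.3-fold), Ctsr (adjusted p = 0.00576, no fold given as IVS day 0 was not above background), the nuclear receptor gene Pparg (22.0-fold), the keratin gene Krt14 (30.4-fold), Myl4 (87.7-fold), Shroom1 (9.97-fold), Serpinb6b (20.4-fold) and Prl4a1 (82.5-fold). Sox2 fell 261-fold (log2 -8.03, SE 0.26, adjusted p = 0.00438), and Cyp26a1 (111-fold), Zic3 (adjusted p = 0.00704, no fold given as WT day 6 was not above background), Ccdc3 (92.4-fold), Dok2 (19.8-fold), the Wnt pathway factor gene Tcf7l2 (21.0-fold), Bves (47.3-fold), Pth1r (14.3-fold), Kifc2 (23.4-fold) and Vwa7 (6.86-fold) fell as well. The SD of the IVS day 0 arrays was 2.45 for Ctsj and 1.56 for Sox2, a spread that their SEs do not use. Of 10 stem cell genes 8 fell and 2 rose, of 10 giant cell genes 8 rose and 1 fell, and of 11 spongiotrophoblast genes 6 rose. These counts were identical when adjusted over each list alone. Of 9 syncytiotrophoblast genes 3 rose, 5 adjusted over the list alone. The counts that rose and fell were 1 and 3 for pluripotency genes, 4 and 1 for X-linked placental genes, 2 and 1 for germline genes, 2 and 0 for escape genes, 1 and 1 for fibroblast markers and 1 and 0 for control genes, the same adjusted over the list alone. They were 5 and 1 for X-linked housekeeping genes (3 and 1 adjusted over the list alone), 1 and 1 for primitive endoderm genes (1 and 2), 2 and 0 for imprinted genes (2 and 1) and 4 and 2 for the Polycomb list (4 and 3). No gene of the X-inactivation centre passed.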

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

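All tests weighed in this part were chosen after the results had been seen. Genes with opposite directions in the compared groups are given first. With 1 sample per group, these differences were not tested. A value against a sample that was not above background on either array is marked as such, with the smallest fold that the background allows.

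Prl6a1, a placental prolactin-family gene of giant cells, stood apart in both comparisons. It was above background on both arrays of IVS day 0 and of WT day 6 and on no other array, so each of its differences is taken against background and only bounds were measured. Its IVS minus WT difference was 5.77 at day 0 (at least 35.5-fold higher) and -3.81 at day 6 (at least 7.27-fold lower). Its day 6 minus day 0 difference was 4.68 in WT (at least 16.7-fold higher) and -4.89 in IVS (at least 15.4-fold lower). The change of the line difference, -9.58, was picked out by a fit to all 8 arrays, but its size is a value against background and no p is given for it. Eomes, a transcription factor gene of stem cells, differed between IVS and WT by -1.32 at day 0 and 1.33 at day 6, where 1 of 2 WT arrays was above background, Lonrf3 by 0.98 and -1.49, and Ly6e by 0.91 and -0.85. Fbp2 differed by 2.2 at day 0 and by -2.5 at day 6, where IVS was not above background (at least 1.42-fold lower), and Matn2 by -1.46 at day 0 and 3.97 at day 6, where WT was not above background (at least 5.85-fold higher). From day 0 to day 6, Gusb differed by -0.81 in WT and 1.02 in IVS. Tceal3 differed by -1.51 in WT, where day 6 was not above background (at least 1.89-fold lower), and by 1.3 in IVS.

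Probes without a gene name, of which the report used only those in the authors' table, held differences as well. At least 1.5-fold higher in IVS were 2386 of 14488 such probes at day 0 and 2006 of 11693 at day 6, and 2126 and 2475 were lower. The unnamed probes of the authors' table exceeded the autosomal median by 0.033 at day 0 and 0.03 at day 6.

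The higher level of X-linked genes in the IVS line was weighed against technical explanations. Intensity-dependent scaling is argued against at day 6 for detected genes, whose lower excess under quantile normalization and normexp was 0.19 (SD 0.049 over pairs of arrays). With no filter on dim probes the day 6 excess was only 0.09, so the point does not extend to dim genes. At day 0 the lower excess was 0.072 (SD 0.07), which leaves that explanation open. Whole-chromosome differences between the cell lines could account for an excess of this size, since 6 autosomes at day 0 and 4 at day 6 lay at least as far from the autosomal median as the X, although chromosome 7 at day 0 did so through only 1 part (0.341 and -0.09 on either side of its middle gene). Incomplete silencing of the X that carries the mutant Xist allele predicts a low place for the escape genes among X-linked lists; their medians stood at percentiles 74.53 and 38.39, which decides nothing with 9 and 7 genes. The data thus suggest a modest X-linked excess whose link to the mutation remains untested, since each genotype is 1 line.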

How the results depend on the processing

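The alternatives that leave out the IVS arrays alone, and all those of the X-linked minus autosomal median, were chosen after the data had been seen. No paired analysis was possible because the labels give no replicate numbers, apart from the additive fit, which compares the lines within each day. Of 301 comparisons of a main value with an alternative, 186 were unchanged, 101 moved and 14 reversed. Of 305 values of named genes, 5 reversed, where only genes at least 1.5-fold apart with arrays that did not overlap could count. Leaving out an array or changing the filter on dim probes could therefore reverse none. Neither could move a value by more than the SD of its arrays. That all 305 stayed the same there was thus fixed in advance and says nothing about how stable they are. The named values that reversed or moved by more than the SD of their arrays numbered 142 with normexp, 107 with no scaling, 55 with control-gene scaling, 49 with quantile normalization, 31 with the mean of a gene's probes and 14 with autosomal scaling. Where no cause is named below, the cause was not tested. Signal over background limited the dim genes, since 51.83% to 65.83% of probes were well above background.

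The X-linked median of IVS minus WT at day 0 (0.19) was -0.012 with no scaling, -0.065 with control-gene scaling, 0.132 with quantile normalization, 0.395 with no filter on dim probes, 0.105 in the authors' table, and 0.176 to 0.322 with an array left out. At day 6 (0.285) it was 0.653, -0.154, 0.185, 0.13 and 0.425 in the same order, 0.228 with normexp, and 0.2 to 0.35. The X-linked minus autosomal median was 0.193 at day 0 and 0.09 at day 6 with no filter, against 0.101 and 0.22, and 0.086 to 0.226 and 0.13 to 0.274 with an array left out. The 88 X-linked genes higher at day 0 became 151 with no filter, 47 at 2-fold and 100 to 131, and the 43 lower 65 with control-gene scaling, 26 with normexp, 22 with the filter on all arrays, 29 at 2-fold and 53 to 68. At day 6 the 88 higher became 141 with no scaling, 41 with control-gene scaling, 48 at 2-fold and 95 to 116, and the 38 lower 76 with control-gene scaling, 58 with no filter, 29 at 2-fold and 41 to 60. Xist at day 0 (-0.445) was -0.647 with no scaling, -0.6 with quantile normalization, -0.7 with control-gene scaling and -0.582 to -0.307. At day 6 (-0.481) it was -0.113, -0.663, -0.92, -0.36 in the authors' table and -0.518 to -0.445. The genes near Xist minus the others (-0.135) gave 0.031 with no filter, 0.14 in the authors' table, -0.026 with the filter on all arrays and -0.212 to -0.173, and at day 6 (-0.077) 0.08 in the authors' table and -0.216 to -0.166.

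The X-linked median from day 0 to day 6 in WT (-0.026) was -0.924 with no scaling, -0.146 with autosomal scaling, -0.095 with quantile normalization, 0.087 with control-gene scaling, 0.19 with normexp, 0.459 with no filter, 0.182 with the filter on all arrays, 0.38 in the authors' table and -0.067 to 0.008. In IVS (-0.056) it was -0.385 with no scaling, -0.216 with autosomal scaling, 0.108 with no filter, 0.099 with the filter on all arrays, 0.515 in the authors' table and -0.141 to 0.063. The X-linked minus autosomal median in WT (-0.157) was -0.129 with quantile normalization, -0.073 with normexp, 0.137 with no filter, -0.01 with the filter on all arrays and -0.196 to -0.139, and in IVS (-0.164) -0.01 with no filter and -0.287 to 0.029. Genes 2-fold higher in WT (1730) numbered 532 with no scaling, 3237 with no filter, 3026 at 1.5-fold and 1855 to 1876, and those lower (1363) 3943 with no scaling, 701 with normexp, 807 with the filter on all arrays, 2191 at 1.5-fold and 1451 to 1660. In IVS the higher (1494) were 939 with no scaling, 2560 at 1.5-fold and 1487 to 2130, and the lower (1208) 1836 with no scaling, 597 with normexp, 734 with the filter on all arrays, 1900 at 1.5-fold and 1847 to 1858. The change of the line difference over X-linked genes (0.043) was 0.613 with no scaling, -0.141 with control-gene scaling, -0.141 with no filter, 0.25 in the authors' table and -0.053 to -0.014. Its spread was widened to 16 pairings of arrays after the verdicts had been seen.

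Genes past the additive fit for the line (542) numbered 877 with no scaling, 296 with autosomal scaling, 1229 with normexp, 1076 with no filter, 330 with the filter on all arrays, 0 without trend, 2417 with 8 arrays and the sample as a block (whose estimated correlation of -0.00363 left the 2 arrays of a sample to count as independent), and 0 to 926 with an array left out. For the day (2496) they were 0 without trend, 5044 with the block and 402 to 1520. Of the passing day genes, 54.6% were higher with autosomal scaling and 54.7% with quantile normalization, against 66.2%. Named genes that reversed were Nap1l2 (0.28 in WT), Sox17 (0.47 in WT) and Cebpa (0.09 in IVS) with normexp, and Eif2s3x (-0.04 in WT) and Xlr (-0.18 in WT) with no scaling, all for the change between days.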

Other observations

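The lists and tests of this part were chosen after the data had been seen, except the test of a mixture on IVS day 0 array 1, whose prediction was written first. The gene lists added here were not run under other scalings. With no scaling, the IVS minus WT median of all genes at day 6 moved from 0.07 to 0.44. Interferon-stimulated genes were lower in the IVS line at both days, 11 of 13 detected at day 0 (median -1.95) and 10 of 14 at day 6 (median -1.54), with none higher and both medians below every random list. Isg15 differed by -5.58 and -3.11, Oasl2 by -5.03 and -2.2, and the immunoproteasome gene Psmb8 by -5.01 and -4.34. Epithelial junction and epithelial transcription factor genes were also lower, 9 of 19 at each day against 2 and 1 higher (median -0.73 at each day). The 9 were not all the same genes, since Elf3 and Cldn3 counted as lower only at day 0, and Ovol1 and Esrp1 only at day 6. Counted at both days were, among others, the transcription factor gene Grhl2 (-3.07 and -1.81) and the cadherin gene Cdh1 (-0.73 and -2.69). Mesenchymal genes had 6 of 15 higher and 1 lower at day 0 (median 0.2) and 5 of 14 higher and 2 lower at day 6 (median 0.0), with Cdh11 at least 3.54-fold higher at day 0. This list differed more between the 2 arrays of IVS day 6, by a median of 1.17 with 9 of 13 genes higher on array 1, than between the lines. The fibroblast feeder markers had medians of 2.35 and 2.64 between the lines and of 2.98 between those arrays.

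Mitotic genes were at least 2-fold lower at day 6 than at day 0 for 14 of 15 in WT (median -2.16) and 12 of 15 in IVS (median -1.79). Between the lines, counted at 1.5-fold as above, their medians were -0.71 at day 0, with 1 lower, and -0.37 at day 6, with 2 lower. The day 0 value is smaller than the gap between the 2 arrays of IVS day 0, where all 15 were at least 1.5-fold lower on array 1 (median -1.81). Cholesterol synthesis genes had a median of -0.31 at day 0, with 1 of 11 lower, and of 0.92 at day 6, with 9 of 11 higher in IVS, such as Hmgcs1 (-0.72 and 0.87) and Sqle (-0.12 and 0.78). Their medians also differed between arrays of 1 sample, by -0.39 in IVS day 0, -0.41 in WT day 0 and -0.37 in IVS day 6, more than the day 0 value between the lines.

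In 5 autosomes (3, 10, 13, 14 and 15) the median gene lay apart from the autosomal median at both days, by at least 0.208, and they were picked for that distance. The 19 autosome medians had a Pearson r of 0.956 between the days. This r covers all 19, so picking the 5 did not build it in, although it was computed after the pattern had been seen. The days lie on separate slides. The IVS arrays held positions 3 and 4 on the day 0 slide and positions 1 and 2 on the day 6 slide. The r thus argues against noise of a slide or of a position on it. Noise of arrays is argued against by the arrays of 1 sample, between which the 19 medians had an SD of 0.01 to 0.038. No other test of slide noise was made. A cluster of changed genes on only 1 side of the middle gene of each of the 5 is argued against too. With each chromosome cut there, the smallest distance of a part was 0.191. Counted at each day, 20 of 20 parts lay outside the range of random lists. The 12 of 56 parts of the other autosomes are no fair contrast, since the 5 were picked for their distance. The cut cannot exclude a cluster that spans the middle gene or clusters on both sides. Shifts of a part do occur, since those of chromosome 7 lay at 0.341 and -0.09 at day 0 and at 0.278 and -0.109 at day 6. The largest move of the 5 between days was 0.115, less than their smallest distance of 0.208, which argues against a different point on the course from day 0 to day 6; a difference in chromosome number is an untested hypothesis, as copy number was not measured.

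The difference between the arrays of each sample was set against the change between days in the other line. Array 1 minus array 2 had a Pearson r across genes of 0.45 for IVS day 0 and -0.11 for IVS day 6 with the WT change, and of -0.01 for WT day 0 and 0.09 for WT day 6 with the IVS change, so random hybridisation error is argued against for IVS day 0. A fixed share of day 6-like RNA in array 1 is argued against, since genes lower at day 6 put the share at 62.9% (interquartile range 31.3 to 80.6) and genes higher at day 6 at 9.7% (3.4 to 22.9). No other biological explanation was tested, and a culture at an intermediate stage remains possible.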
